A study of Caenorhabditis elegans with 2 samples.

How the data were processed

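Chromatin immunoprecipitation with sequencing (ChIP-seq) maps where a protein sits on the genome: chromatin is cross-linked and broken up, the fragments that carry the protein are pulled down with an antibody, and the recovered DNA is sequenced. The samples here were 2 biological replicates of whole Caenorhabditis elegans mid-embryos, 3.5 hours old per the labels, from 1 transgenic strain. The precipitation used an antibody against green fluorescent protein (GFP), which recognises a GFP tag on the transgenic protein. The labels call the target tab-1, a homeobox gene, while the genotype in the same labels puts the tag on T27A8.2 and adds a working copy of unc-119. These are different genes in the annotation used here, so the samples are called "labelled tab-1" throughout. The labels point to a control experiment, whose data were not used here.

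The deposited files were peak lists on the ce11 build, per the submitters' processing notes. For each replicate, and for both replicates together, there was a list of ranked candidates and a list past a threshold on the irreproducible discovery rate (IDR), which estimates the share of irreproducible peaks from how well 2 sets of peaks rank alike. Together the replicates had 2 such pairs of lists. The authors' conservative list of 1313 peaks was the main list. All of its peaks (100%) were found in 1 ranked list, whose columns also hold the signal of each replicate's own peaks, and 55.4% in the other ranked list. The lists of a single replicate and the other list of both replicates served as alternatives. Aligner, peak caller, their versions and the read depth are not given in the sources used here, so no interval that needs the depth is given.

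Each peak carries a signal value from the authors' peak caller, whose scale is not stated. It was used only to rank, describe or filter peaks within a list, or to correlate sites between the replicates. The deposited score falls as the IDR rises, and the ranked lists as deposited by the authors also give the −log10 of the global IDR; the tie between these columns was read from their values. The lowest score in each thresholded list was 830, which lies at a global IDR of 0.01 on this scale. The thresholded lists derive from 1 further file, per the deposited notes, and leave out some candidates that pass the same score: 124 of 1437 for the conservative list. No p-value or q-value of a single peak was read from the thresholded lists.

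Chromosome lengths of the reference (WBcel235, the same assembly as ce11) were compared with the largest peak ends: none of the 6 nuclear chromosomes had a peak beyond its end. Gene models came from Ensembl release 115, and tRNA isotypes from the RefSeq annotation of the same assembly by WormBase gene number. Coordinates are given 1-based on WBcel235. Peaks that overlap by at least 1 bp were merged into a site, which kept the signal and summit of its strongest peak. Mitochondrial peaks were left out of every comparison. A promoter was the stretch from 1000 bp before to 200 bp after the 5′ end of any transcript of a protein-coding gene. Each summit got the first class that applied among promoter, 5′ UTR, coding exon, 3′ UTR, intron, non-coding gene and intergenic. A site was at a tRNA, snoRNA, snRNA or miRNA gene when its summit lay within 200 bp of it. Sites at any of these 4 kinds are called small RNA gene sites below, and a site near several kinds was given to the first of them in that order. The remaining sites can still lie at other non-coding RNA genes or at pseudogenes.

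Shares of sites were compared with 9999 random relocations of the summits within their chromosomes, counting the observed value as 1 further draw, so that the smallest p is 0.0001 one-sided and 0.0002 two-sided. The overlap of the replicates' own lists was compared with 9999 draws of as many sites from each replicate's merged candidates. Spearman and Pearson correlations across sites had a permutation p from 100000 resamples, the smallest being 1e-05. The share of sites on the X chromosome had an exact two-sided binomial test against the X share of protein-coding genes. Intervals of shares are 95% Wilson intervals and cover counting error over sites only. The 25 gene lists were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. The background was the set of protein-coding genes with at least 1 ranked candidate in the promoter window. DNA words were looked for on both strands in the 201 bp around each summit and in a window of the same width centred 500 bp to one side, drawn at random. The exact McNemar test, two-sided, was adjusted with Benjamini-Hochberg over 16 preset words and over 2080 words of 6 letters. TATTAA and TTAATA, preset as controls of the same composition as TAATTA, are each other's reverse complement and so gave 1 and the same value.

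The main tests, the lists, the words and most alternatives were fixed before the data were examined. Those added later are named in the closing section or beside their values. The planned stricter IDR of 0.01 is the authors' own threshold and removed no peak, so an IDR of 0.001 was added. The text names tab-1, T27A8.2 and unc-119; the 20 sites of highest signal with the genes at them; up to 4 members with the strongest promoter site of each list past an adjusted p of 0.05, and up to 2 of any other list named; the 3 strongest sites of each replicate's own list that the other's list lacks; and the 10 words of smallest p. Names outside this rule are said to be chosen after their values were seen.

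The list test and the word scan were tested on simulated data. Over the 12835 background genes, lists whose rate of sites was raised 4-fold were recovered in 47 of 60 cases and those raised 2-fold in 14 of 60, while of 440 unchanged lists tested beside the 4-fold ones 1 was called. Over the 2080 words, 10 of 10 words planted in 10% of windows were recovered and 5 of 10 planted in 5%, and with none planted 0 were called. With words planted in 10% of windows, 21 others were called; planting also overwrites bases and makes words that overlap the planted ones, and these were not counted apart. Both windows of each simulated pair lay away from the summits, so they lack the difference in G and C content between real summits and flanks. Simulated genes got their sites independently, while a real site can lie in the promoter windows of 2 genes. The rates of false calls therefore do not carry over to the real tests in these respects. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.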

Results

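The data are lists of genomic sites recovered with an antibody against GFP from C. elegans mid-embryos, in 1 group of 2 biological replicates labelled tab-1. The question the design poses is where in the genome the tagged protein is found and how well the replicates match. The main list held 1313 peaks, which merged into 1266 sites covering 368.4 kb of the nuclear genome, with a median width of 304 bp; 47 sites joined more than 1 peak. Their signal, in the authors' units, had a median of 94.1 per peak and ran up to 1129. Replicate 1's own list gave 453 nuclear sites and replicate 2's own list 726. The read depth is unknown, so these numbers cannot be set against sequencing effort.

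Most of the strongest sites lay at small non-coding RNA genes. Of the 1266 sites, 250 (19.7%, 95% interval 17.6 to 22) had their summit within 200 bp of a tRNA gene, the genes for the adaptors of translation, against 0.297% after random relocation, a 66.5-fold excess. Another 61 sites (4.82%, 3.77 to 6.14) lay at snoRNA genes, whose RNAs guide the modification of ribosomal RNA, a 25.8-fold excess over the 0.187% after relocation. Counted by gene, 271 of the 612 annotated nuclear tRNA genes (44.3%) and 62 of 346 snoRNA genes (17.9%) had a site. The one-sided permutation p from the relocations was 0.0001 for both kinds, the smallest the draws can give. The shares were larger in the shorter lists: tRNA genes took 38.9% of replicate 1's own sites and 32.1% of replicate 2's, and snoRNA genes 10.6% and 7.99%.

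Smaller numbers of sites lay at the other kinds of small RNA. There were 11 at snRNA genes (0.869%, a 15-fold excess) and 10 at miRNA genes (0.79%, 6.37-fold), each with a one-sided permutation p of 0.0001. Taken as 1 class, small RNA gene sites made up 331 of the 1266 (26.1%, 23.8 to 28.6), with a median signal of 183 against 87.1 for the other 935 sites. Drawing from the ranked candidates in place of random positions gave an expected share of 0.488% for tRNA genes and 0.286% for snoRNA genes, again with a one-sided permutation p of 0.0001.

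The excess was steepest among strong sites. Among the 100 sites of highest signal, 50 were at tRNA genes (50%, 40.4 to 59.6) and 31 at snoRNA genes (31%, 22.8 to 40.6). These shares were 49% and 8% in the next 100 sites, 39% and 6% in the 200 after those, 14.8% and 0.75% in the 400 after those, and 3% and 1.5% in the last 466. Promoters of protein-coding genes, which can hold small RNA genes too, took 29%, 41%, 41.5%, 42.5% and 35.4% of the sites in the same bins.

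**Figure D1:**
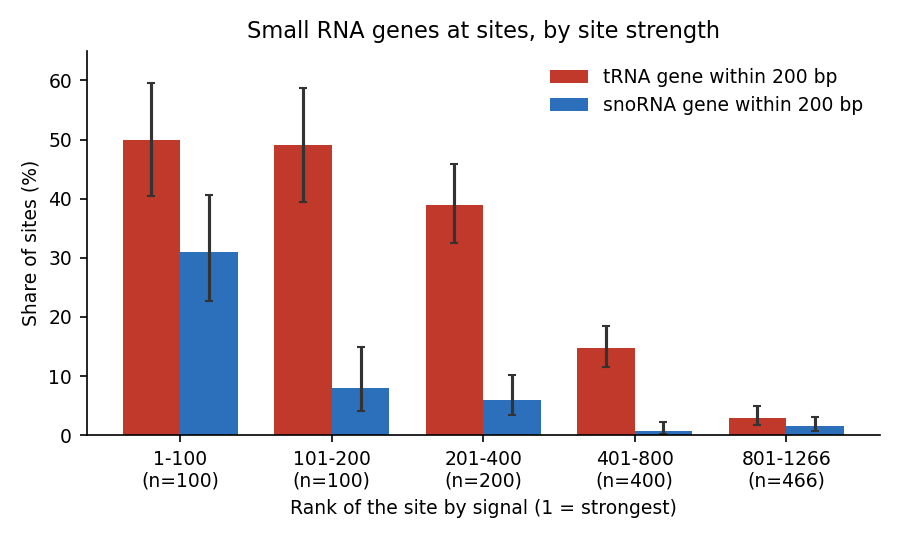
Share of sites (%) whose summit lies within 200 bp of a tRNA gene (red) or a snoRNA gene (blue), in bins of the site's rank by signal (1 is the strongest); bars are shares and error bars 95% Wilson intervals. The tRNA share falls from 50% in the top 100 to 3% beyond rank 800, and the snoRNA share from 31% to 1.5%.

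Among the 20 strongest sites, 9 were at snoRNA genes, 9 at tRNA genes and 1 at a miRNA gene; 11 summits lay in introns of protein-coding genes, 4 in promoters, 3 in non-coding genes and 2 between genes. The strongest, with a signal of 1129, spanned 12303469 to 12303782 on chromosome V, in an intron of frm-7 beside the snoRNA genes C51F7.3 and C51F7.4; the nearest protein-coding 5′ end was that of F55C5.17. Its summit sequence, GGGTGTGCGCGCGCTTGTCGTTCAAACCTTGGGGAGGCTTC, is centred on position 12303639. The second, with a signal of 1026, spanned 11960675 to 11961001 on chromosome II, between genes and beside the snoRNA gene W03C9.9, with W03C9.1 as the nearest 5′ end.

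Further snoRNA gene sites among the 20 were ZK265.10 in the promoter of the chemoreceptor gene sre-23 (signal 908, summit at 8259559 on chromosome I) and T06C12.16, nearest to str-56 (signal 864, summit at 15873976 on V). T03F7.8 lay in an intron of cutl-18 (signal 800), ZK994.7 in an intron of pxn-1 (681), Y43F8C.22 in an intron of Y43F8C.7 (572) and B0334.12 in an intron of the potassium channel gene twk-5 (505). T02E1.9 lay in the promoter of T02E1.2 with a signal of 563. At rank 7 came cel-mir-51 in a non-coding gene on chromosome IV, at 11025895 to 11026348, nearest to the 5′ end of hrg-5 (679).

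The tRNA genes at the 20 strongest sites read several amino acids. On the X chromosome they were a leucine tRNA gene nearest to C04A11.5 (signal 613, 13665440 to 13665722), an asparagine tRNA gene in an intron of sulp-3 (565), a glycine tRNA gene in an intron of snx-17 (559) and a tyrosine tRNA gene in an intron of nhr-17 (532), for which nlp-76 had the nearest 5′ end. A lysine tRNA gene nearest to col-181 (515) and a pair of alanine tRNA genes in an intron of him-4 (513), with F15G9.5 as the nearest 5′ end, were also on X. An arginine tRNA gene lay in an intron of the collagen gene col-99 (539), and an isoleucine tRNA gene in the shared promoter region of gcy-33 and cpr-9 (527). The last was a tryptophan tRNA gene in an intron of fli-1 (510), nearest to the 5′ end of pgl-2. The one site of the 20 away from small RNA genes was in the promoter of K12H4.5 on chromosome III, at 8043866 to 8044079, with a signal of 529. Of the 20 sites, 19 were in both replicates' own lists; the lysine tRNA site was in replicate 2's list but not in replicate 1's.

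The replicates shared most of their strong sites. Of replicate 1's 453 sites, 362 (79.9%, 76 to 83.3) overlapped a site of replicate 2, and of replicate 2's 726 sites, 363 (50%, 46.4 to 53.6) overlapped one of replicate 1. Replicate 2's list is the longer, which by itself limits the share of it that replicate 1's list can match. The same limit holds for the classes of site given below. Random draws of as many candidates from each replicate shared 0.762% and 0.476%, and at most 2.87% and 1.79%, so that the one-sided permutation p was 0.0001, the smallest the draws can give. Sites at tRNA genes were shared by 169 of 176 in replicate 1 (96%) and by 170 of 233 in replicate 2 (73%), and sites away from small RNA genes by 137 of 219 (62.6%) and 137 of 420 (32.6%).

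Signals of shared sites rose together. Across the 362 shared sites the Spearman correlation of the replicates' signals was 0.86 and the Pearson correlation 0.93, both with a permutation p of 1e-05, the smallest the resamples can give. Over the 1266 sites of the main list, using the 2 columns of replicate signal that the ranked list carries, these were 0.58 and 0.93. Within the 331 small RNA gene sites the Spearman and Pearson correlations were 0.89 and 0.95, and within the other 935 sites 0.26 and 0.82. Across the 137 shared sites away from small RNA genes they were 0.74 and 0.82. Each had a permutation p of 1e-05. These are correlations across sites, which are not independent replicates. Both sets of sites were also selected through the replicates, the shared sites for being in both lists and the main list for ranking alike, so the correlations do not describe unselected peaks.

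**Figure D2:**
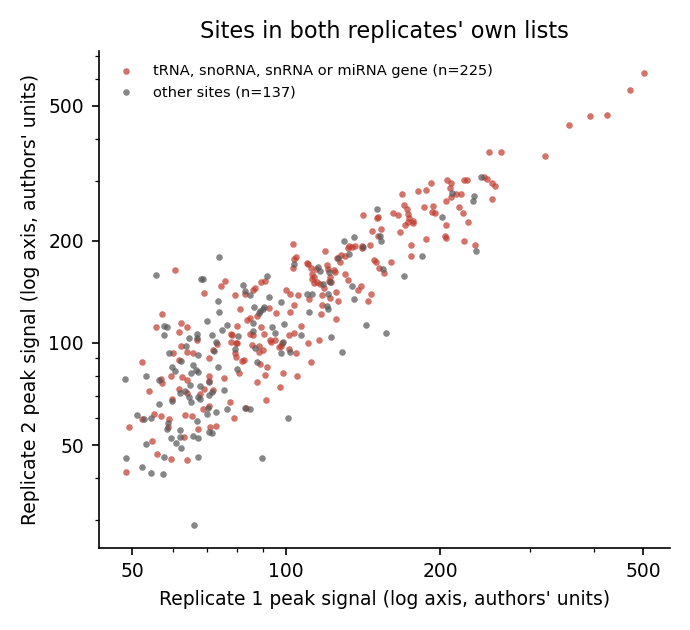
Peak signal in replicate 1 (x, log axis) and replicate 2 (y, log axis), in the authors' units, for the 362 sites in both replicates' own lists; each point is a site, red at tRNA, snoRNA, snRNA or miRNA genes (n = 225) and grey elsewhere (n = 137). The points follow a rising line (Spearman 0.86), with red points at the strong end.

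Each replicate's own list was thresholded separately, so absence from it does not by itself measure agreement between the replicates. Those lists held only part of the main list. Of its 1266 sites, 358 (28.3%) were in both replicates' own lists, with a median signal of 211, and 224 of these (62.6%) were small RNA gene sites. Another 617 sites (48.7%) were in neither replicate's own list, with a median signal of 80.4, and 39 of these (6.32%) were small RNA gene sites. The strongest sites of replicate 1 that replicate 2's list lacked were between genes, nearest to Y51H7C.13 on chromosome II (signal 91.4), at an arginine tRNA gene in an intron of col-54 on I (84.6) and in an intron of Y51F10.4 on I (83.6). For replicate 2 they were at the lysine tRNA gene nearest to col-181 (305), in the promoter of the ribosomal protein gene rpl-3 (149) and in that of eif-3.C, which encodes a translation initiation factor subunit (127). All 6 were in the main list. Among unshared sites, small RNA gene sites were 9 of 91 in replicate 1 (9.89%) and 80 of 363 in replicate 2 (22%, Fisher's exact test, two-sided, p = 0.00779). This comparison was not among the planned tests. Replicate 2's own list is the longer and was thresholded separately, so this p-value does not measure a difference between the replicates.

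Promoters of protein-coding genes held 488 of the 1266 summits (38.5%, 35.9 to 41.3), against 25.7% after relocation, a 1.5-fold excess (two-sided permutation p = 0.0002, the smallest the draws can give). Coding exons held 83 summits (6.56%, 5.32 to 8.06), against 18.8% of the genome. Introns held 348 (27.5%), against 27.7% of the genome. The classes differed between kinds of site. Among the 935 sites away from small RNA genes 406 were at promoters (43.4%, 40.3 to 46.6, two-sided permutation p = 0.0002). Among the 331 small RNA gene sites 82 were (24.8%, 20.4 to 29.7) and 141 were in introns (42.6%, 37.4 to 48.0). Small RNA gene sites were picked for lying near such genes, so these shares show no preference beyond where the genes lie.

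**Figure D3:**
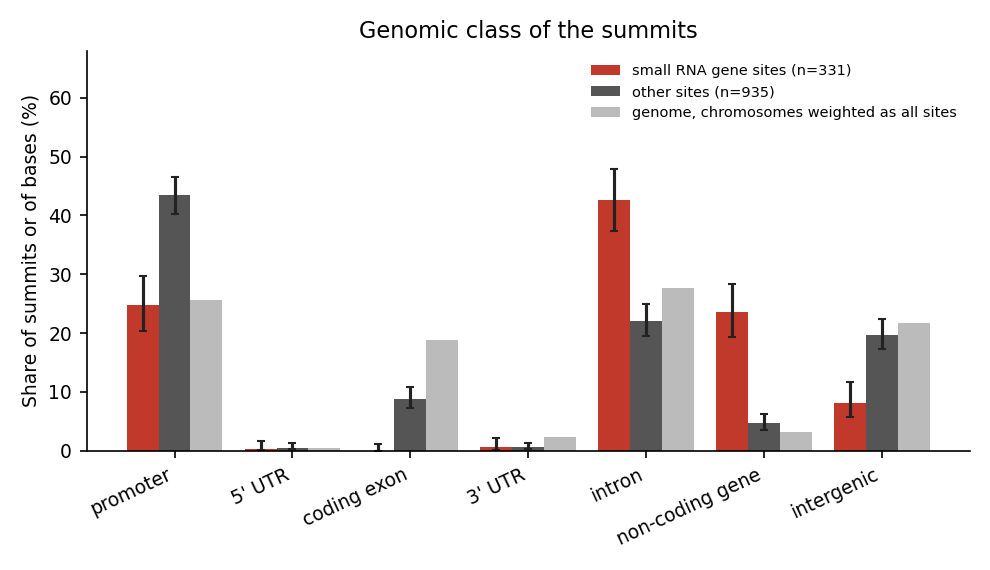
Share (%) of the summits of small RNA gene sites (red, n = 331) and of other sites (dark grey, n = 935) in each genomic class, with 95% Wilson intervals, and the share of the genome's bases in that class (light grey, chromosomes weighted as all 1266 sites). Other sites stand above the genome at promoters (43.4% against 25.7%), and small RNA gene sites at introns (42.6%) and non-coding genes (23.6%). The latter sites were picked for lying near small RNA genes, so their classes follow from where those genes lie.

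The X chromosome held more sites than its genes would give. It had 284 of the 1266 sites (22.4%, 20.2 to 24.8), against 13.7% of protein-coding genes (exact binomial test, two-sided, p = 2.89e-17), 15.7% of the ranked candidates and 17.7% of the nuclear genome's length. Of the 250 tRNA gene sites 40.4% were on X (34.5 to 46.6), where 45.1% of the annotated tRNA genes lie. A site was present at 111 of 276 tRNA genes on X (40.2%) and 160 of 336 on the autosomes (47.6%; Fisher's exact test, two-sided, p = 0.0722). Without small RNA gene sites X held 182 of 935 (19.5%, 17.1 to 22.1), above its share of genes (exact binomial p = 8.73e-07), while its share of the length lies inside this interval. Chromosome V held 179 sites (14.1%, 12.3 to 16.2) with 25% of the protein-coding genes.

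Genes with a site in their promoter were enriched in lists of ribosomal proteins, translation, respiration and splicing, and scarcer among chemoreceptors and among the F-box, MATH and C-type lectin families. There were 591 such genes among the 12835 of the background (4.6%). Cytosolic ribosomal protein genes had a site in 12 of 76 members (15.8%; Fisher's exact test, adjusted p = 0.00423), translation factors in 7 of 36 (19.4%; 0.0086), mitochondrial respiration genes in 8 of 47 (17%; 0.0086) and splicing and snRNP genes in 6 of 39 (15.4%; 0.0398). Sites were scarcer at the F-box, MATH and C-type lectin families (6 of 398, 1.51%; 0.0086) and at chemoreceptors (12 of 511, 2.35%; 0.0398). All are from Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 25 lists.

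The strongest promoter sites among ribosomal protein genes were at rpl-3 (signal 220, summit at 3867558 on III), rpl-15 (200), rpl-35 (177) and rps-28 (172). Among translation factors they were at eif-3.C (177, summit at 9979899 on I), the elongation factor gene eef-1A.2 (144), eif-3.I (106) and eef-1A.1 (rank 532 of all sites, also at a miRNA gene). Respiration genes with the strongest sites were the cytochrome oxidase genes cox-6A (187), cox-5B (155) and cox-6B (126), and the ATP synthase gene atp-1 (rank 442); the cox-6A summit also lies at an snRNA gene. Splicing genes were led by snr-1 (135), prp-19 (124), snr-4 (118, also at an snRNA gene) and rsp-1 (92.5, a site shared with rsp-2). Among chemoreceptors the strongest were sre-23, sre-1 (255), srh-269 (197) and srbc-38 (153), and in the F-box, MATH and C-type lectin families clec-126 (229), fbxc-44 (192), clec-53 (153) and math-33 (138); sre-23 lies at a snoRNA gene site, and srh-269 and clec-126 at tRNA gene sites.

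Lists of transcription factors did not pass the adjusted threshold. Homeobox genes had a site in 4 of 75 members (5.33%; Fisher's exact test, adjusted p = 0.973), with ceh-39 (signal 93.4) and ceh-2 (91.7, at a tRNA gene) the strongest, and touch receptor neuron genes in 0 of 14. Nuclear hormone receptors had 4 of 154 (2.60%; 0.634), led by nhr-255 (394) and nhr-41 (225), both at tRNA gene sites. Histone genes had 6 of 49 (12.2%; 0.0864), led by his-67 and his-68 (97.7, a single shared site), and chaperone genes 5 of 47 (10.6%; 0.199), led by dnj-29 (267) and hsp-60 (240). Both passed in the authors' other list (Fisher's exact test, adjusted p = 0.00336 and 0.00206) and in replicate 2's own list (0.0131 each). Proteasome genes (1 of 31), vacuolar ATPase genes (0 of 20) and cell cycle genes (4 of 66) did not pass. Without small RNA gene sites, an alternative chosen after the data were seen, 2 lists stayed enriched, ribosomal proteins (Fisher's exact test, adjusted p = 0.000873) and translation factors (0.0282), and the F-box group stayed scarce (0.0282). The other 3 lists lost their call with odds ratios that changed little: respiration 3.63 from 4.29 (adjusted p = 0.0578), splicing 3.65 from 3.8 and chemoreceptors 0.481 from 0.488 (0.0676 each; Fisher's exact test). No list was enriched in replicate 1's own list, at an IDR of 0.001 or when each site was counted once for its nearest gene, where fewer genes have a site. Ribosomal proteins stood 3.43-fold over the background in the main list, and 1.64-fold, 3.48-fold and 2.91-fold in these; translation factors 4.22-fold, and 3.43-fold, 3.68-fold and 3.07-fold; splicing genes 3.34-fold, and 1.57-fold, 1.7-fold and 2.13-fold. In replicate 2's own list 6 lists were enriched, and the F-box group lost its call with a similar ratio to the background, 0.348 against 0.327 (Fisher's exact test, adjusted p = 0.0642). The F-box group also had no call in replicate 1's own list and at an IDR of 0.001, where its ratio was nearer the background, 0.598 and 0.665. With a promoter window of 500 bp upstream splicing genes lost their call at 2.81-fold (Fisher's exact test, adjusted p = 0.187).

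**Figure D4:**
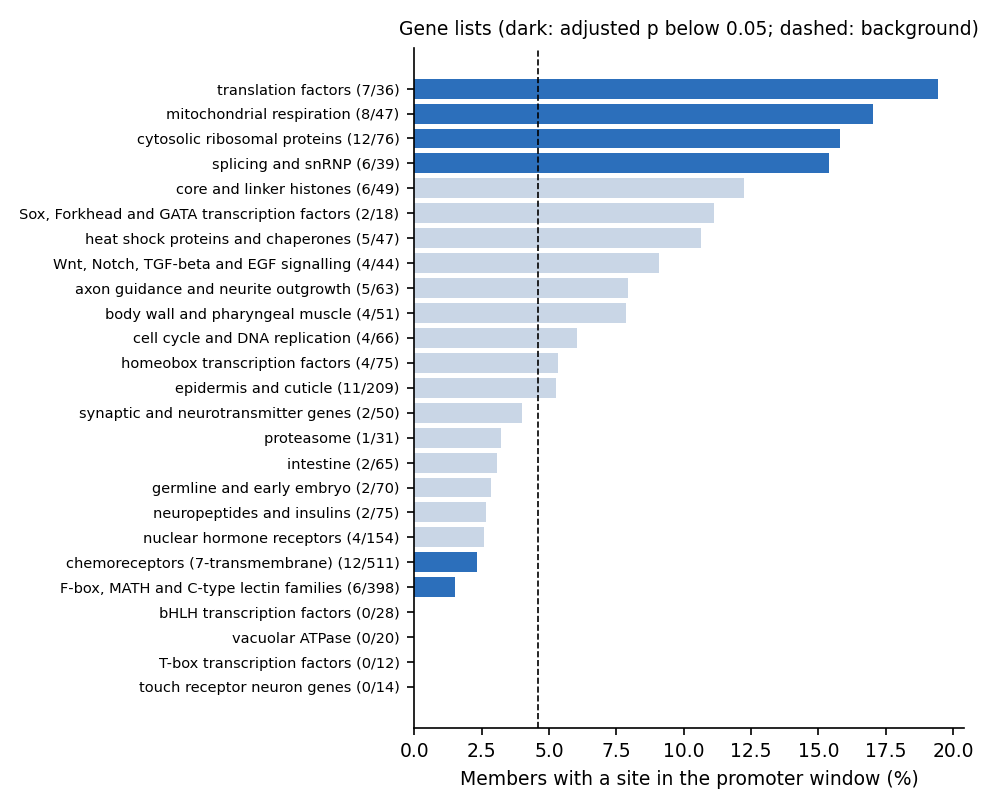
Share (%) of the members of each of the 25 gene lists that have a site in the promoter window, with the number of members with a site over the members in the background; dark bars have an adjusted p under 0.05 and the dashed line is the background share of 4.6%. Translation factors (19.4%) and mitochondrial respiration genes (17%) lead, and 4 lists have no member with a site.

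The sequence at summits was rich in G and C, 48.5% against 36.9% in the flanks, over 1264 pairs of windows. TAATTA, the core that many homeodomains bind, was in 4.75% of summit windows and 8.86% of flanks (exact McNemar test, two-sided, adjusted p = 7.68e-05), a fall of 4.11 percentage points that puts it below the flanks; in replicate 1's own list it fell by 7.28 points. The control word TATTAA, of the same letters, went from 16.9% in flanks to 5.78% at summits (1.33e-18), and the related CAATTA from 13.8% to 7.67% (1.19e-06). CCATTA did not pass (6.88% and 6.09%; 0.535).

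Preset words that were more frequent at summits were led by GTTCGA, part of the internal promoter of tRNA genes (22.2% against 6.88%; exact McNemar adjusted p = 2.97e-27), GAGAGA (25.7% against 10.6%; 1.81e-22), GCGCGC (11.6% against 1.34%; 5.99e-28) and CCGCCC (14.9% against 3.40%; 4.17e-26). The E-box CACGTG was in 4.27% and 3.88% and GATAAG, which GATA factors bind, in 5.30% and 5.85%, with adjusted p of 0.685 and 0.637. The difference for GTTCGA was 15.3 percentage points, and it was 28 in replicate 1's own list and 25.9 in replicate 2's. Without small RNA gene sites GTTCGA differed less and did not pass (7.92% against 6%; exact McNemar adjusted p = 0.134), while GAGAGA (24.5% against 10.7%; 6.74e-15) and GCGCGC (14.2% against 1.39%; 8.16e-26) did.

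**Figure D5:**
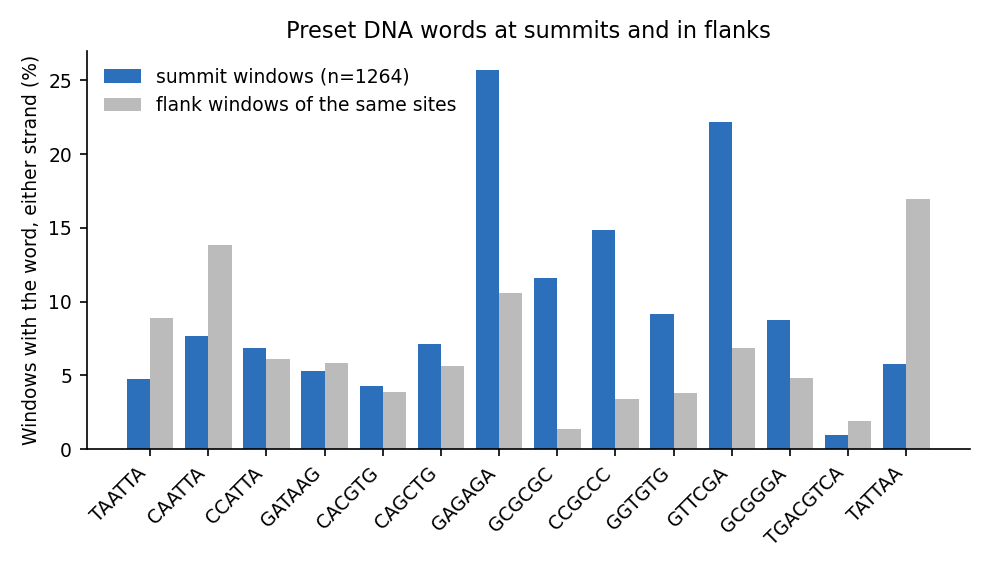
Share (%) of windows with each preset word on either strand, at summits (blue, n = 1264) and in the flanks of the same sites (grey); the second control word, equal to TATTAA read on the other strand, and TAAT (61% and 82.6%) are not drawn. GAGAGA and GTTCGA stand above their flanks, and TAATTA and TATTAA below.

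In the scan of all 6-letter words 685 were enriched at summits and 507 were scarcer. The 10 of smallest p were CGAACC (20.1% of summits against 3.40% of flanks; exact McNemar adjusted p = 1.75e-38) and CGCCGC (16.8% against 3.24%; 1.19e-28), both enriched, and 8 scarcer A- and T-rich words: AAAATT (30.5% against 60.6%; 1.32e-48), AAAAAT, TTAAAA, AAATTA, TAAAAA, CTGAAA, AAAACT and AAATTT. The scarcer A- and T-rich words, and enriched words such as CGCCGC, go with the difference in G and C content between summits and flanks. How much of the counts that difference accounts for was not tested. CGAACC reads GGTTCG on the other strand, which overlaps GTTCGA of the tRNA gene promoter. Without small RNA gene sites the enriched words of smallest p were led by CGCGCA instead.

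The loci named in the genotype and the labels showed no crowding of sites. Within 20 kb of T27A8.2 (WBGene00012074, X, 16057676 to 16058945) there was 1 site, in a coding exon of col-187 with the summit at 16073473 and rank 871 by signal (82.9), against 0.669 after relocation (one-sided permutation p = 0.486). Within 20 kb of tab-1 (WBGene00006380, II, 6803324 to 6804863) there were 0, against 0.577, and within 20 kb of unc-119 (WBGene00006843, III, 10902641 to 10908935) there were 0, against 0.626, each with a one-sided permutation p of 1. These values do not tell which gene carried the tag.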

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

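Every test reported in this part was chosen after the result was seen. Replicate 2's own list held 24 mitochondrial peaks, a signal outside the nuclear comparisons, while replicate 1's list and both lists of the replicates together held none. Their signal had a median of 246 and reached 923, the highest of that list, and 11 of them ranked among its 24 strongest peaks. Their summed widths equal 39.4% of the 13794 bp of mitochondrial DNA. Among the ranked candidates replicate 2 had 25 mitochondrial entries, while replicate 1 and both joint ranked lists had 0. The contrast is thus already present before the threshold, and its cause was not tested.

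The conservative list lacked 124 candidates of its own ranked list that scored past its threshold. They include signals above any in the list: 4800 on X at 15810939 to 15811223, 2108 on X at 11785709 to 11785929 and 1242 on X at 15808083 to 15808292, all between genes. None of the 124 (0) lay at a small RNA gene. Around their summits a median of 88.3% of 12-letter words occurred more than once, with quartiles of 75.6% and 93.7%, against a median of 0% at the 1266 sites kept. They therefore sit in locally repeated DNA. No biological explanation was tested.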

How the results depend on the processing

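Added after seeing the data were the IDR of 0.001, leaving out small RNA gene sites, and all alternatives for snoRNA genes. Under every alternative run, the promoter, X, tRNA and snoRNA shares stayed above and TAATTA below their reference, past the threshold, the Spearman correlation of replicates stayed past it, and the sites near the 3 loci stayed short of it. Sizes moved more: without replicate 1, without replicate 2 and at an IDR of 0.001 the tRNA share was 32.1%, 38.9% and 46.9% and the snoRNA share 7.99%, 10.6% and 12.8%, and TAATTA fell by 2.45 points (against candidates below the threshold) and fell by 7.28 points without replicate 2. The planned IDR of 0.01 moved nothing and says nothing about stability. With 1 replicate left out (the other's own list), the sites numbered 453 to 726, enriched 6-letter words 448 to 571, enriched lists 0 to 6 and scarcer lists 0 to 1; overlap and correlation need both replicates and have no such value. At an IDR of 0.001 there were 390 sites, 415 enriched words, 0 enriched lists and 0 scarcer lists. Leaving out small RNA gene sites gave 2 enriched and 1 scarcer list, and counting each site once gave 0 and 1. Fewer sites enter most of these; the cause was not tested otherwise. Requiring 50% of both peaks, replicates 1 and 2 shared 61.4% and 39.1% of their peaks. Among the 50% of peaks with the highest signal they shared 95.3% and 60.4%, which is 221 of 232 and 221 of 366. Replicate 2's share is bounded by its longer list. Why the shares changed between these settings was not tested. Among single lists and words, 23 values lost a call and 7 gained one. The unknown read depth limits all counts.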

Other observations

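Tests of the B-box word, of repeated stretches, of the X share and of the RNA genes in the next sentences were chosen after the results were seen. Other small structural RNAs also had sites. They are not among the 4 kinds counted as small RNA genes, so sites such as those at rpr-1 and mrpr-1 fall among the sites away from small RNA genes. The RNase P RNA gene rpr-1 (I, 13463955 to 13464207) had a site of rank 65 with a signal of 375, and the RNase MRP RNA gene mrpr-1 (II, 7200233 to 7200418) one of rank 61 with 382. All 5 genes named srpr, for the RNA of the signal recognition particle, had one: srpr-2.2 (265), srpr-2.1 (210), srpr-1.2 (200), srpr-1.1 (172) and srpr-3 (110). The Y RNA gene yrn-1 had none, nor did any of the 20 rRNA genes, and 4 of 30 spliced leader genes and 7 of 99 other snRNA genes had one. Among tRNA isotypes the share of genes with a site ran from 25.9% for glutamine (7 of 27) to 59.3% for aspartate (16 of 27), setting aside the 1 selenocysteine gene and 5 genes with no matched isotype, which had 0; no isotype differed from the rest (Fisher's exact test, smallest adjusted p = 0.80).

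The strongest promoter sites away from small RNA genes, named after their values were seen, include mlcd-1 and idhg-1 on III (signal 491), atx-2 and ecps-1 on III (482), ears-2 and uncp-18 on IV (411), npp-6 and spd-5 on I (335) and T13C5.6 on X (505). The T13C5.6 summit also lies in a non-coding gene (C14F11.14). Several of these summits lie in the promoter windows of 2 genes at the same time. Over all sites away from small RNA genes, at promoters or not, the enriched words of smallest p were CGCGCA (18.2% of summits against 3.10% of flanks; exact McNemar adjusted p = 3.46e-25), GCGCGC and GCGCAC (16.1% against 2.25%; 8.21e-24).

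Some snoRNA genes with sites may have a tRNA-type promoter. The word GTTCRANNC, the B box of such promoters (R is A or G, N any base), lay within 200 bp of 31 of the 62 snoRNA genes with a site (50%, 37.9 to 62.1) and of 45 of the 284 without one (15.8%, 12.1 to 20.5), a ratio of 3.16 (2.19 to 4.55; Fisher's exact test p = 8e-08). For tRNA genes the word was looked for inside the gene only. Of the 588 that hold it 261 had a site (44.4%), and of the 24 that lack it 10 had one (41.7%). This was not tested, and 24 genes are too few to tell whether the word marks those with a site. The 20 tRNA genes with no repeated stretch all hold it and had 0. Away from small RNA genes it was in 10.4% of sites outside promoters and 3.03% of their flanks (exact McNemar adjusted p = 3.1e-06), and in 5.93% of promoter sites and 3.46% of their flanks (0.185).

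For the sites at tRNA genes, the preset prediction of an excess of a homeodomain core word was not met. TAATTA was 0.194 times as frequent at tRNA and snoRNA summits as in their flanks (0.0819 to 0.457). Its control TATTAA, of the same letters, also fell there, to 0.447 times, and CAATTA to 0.146 times, while CCATTA did not (1.23). Because the control fell too, these values show no excess of TAATTA but cannot tell whether a homeodomain is bound. Reads shared between repeated sequences stay open for tRNA genes. Genes of a single sequence had a site 0.60 times as often as genes with an identical copy (42 of 143 and 229 of 469, Fisher's exact test p = 4.87e-05). The interval of this ratio, 0.459 to 0.788, lies on neither side of the preset bound of 0.5. Of the 20 tRNA genes with no 30-base stretch found elsewhere 0% had a site (up to 16.1%), where chance gives 0.617%. Of the 592 with such a stretch 271 had one (45.8%). These rates go with shared reads as the whole cause, but the first rests on 20 genes. For snoRNA genes, 18.5% of 297 genes with no such stretch had a site (14.5 to 23.3), where chance gives 0.686%. This argues against repeated 30-base stretches as the whole cause. Shared reads are not excluded, since the test counts only such stretches and the aligner is unknown. Whether an antibody against GFP would recover these genes without the tagged protein was not tested, since no control library was used here.

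Whether the positions of tRNA genes account for the whole X share depends on the reference and stays open: without tRNA gene sites X held 18% of the remaining 1016 sites (15.8 to 20.5), above its 13.7% of protein-coding genes but not above its 17.7% of the nuclear genome's length. A mislabelled target could show as extra signal at the tagged locus, and this cannot be told apart. The summed signal of candidates within 20 kb of T27A8.2 stood at percentile 54.2 of windows on its chromosome. That of tab-1 stood at percentile 0.669, and neither was above the preset bound. The unc-119 window stood at percentile 62.3, so this measure did not show the copy of unc-119 that the genotype adds either. The tab-1 window held 1 candidate of the main ranked list where the median window on chromosome II held 49, and 8 and 3 candidates in the lists of replicates 1 and 2, where medians were 37 and 30. No candidate of the main ranked list lay between 6783207 and 6824654, a gap of 41.4 kb around tab-1. Of the 16551 gaps on that chromosome 10 are as long, and such gaps hold 3.28% of the chromosome.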
